A study of Homo sapiens with 12 samples.

How the data were processed

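The deposited files held bead array intensity per probe for 12 columns, summarised in BeadStudio per the submitters' processing notes, which give no version, and a series matrix of log2 values from the authors. Total RNA had been made into biotin-labelled cRNA. The files named no background correction and held no detection p-values, and every per-sample column was mapped to a sample (0 left unmapped). The matrix equalled log2 of the 12 quantile-normalized columns to within 5e-04. The siLuc 2 column equalled the mean of siLuc 1 and siLuc 3 at 47231 of 47231 probes, with a largest relative difference of 2.22e-16, and no other column equalled the mean of its group's other 2 at any probe. It was left out, and siLuc values throughout are those of the 2 remaining arrays.

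Deposited intensities were corrected with normexp (offset 50), quantile-normalized over the 11 arrays and taken to log2 in limma 3.58.1 on R 4.3.3. Probes under the 25th percentile of mean normalized signal were left out (11808), which left 35423. The file gave a gene identifier for 43960 probes; 35672 matched the reference gene table, 8790 took an updated symbol from it and 3270 had no symbol. A background bound was set per array at the peak of its log2 signal density plus 3 spreads of the lower side, which gave 127 to 151. Groups were compared with lmFit and eBayes over the 4 groups at once (7 residual and 11.6 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. Target genes also had an exact two-sided permutation test on the normalized values. Signals are given as group means with the SD between arrays, and folds are from means of normalized log2 values, except that a fold given as at least a value is from deposited signals and the background bound.

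The following were fixed before the data were examined: the comparisons, thresholds, gene lists, named-gene rule and most of the settings varied in the part on processing. The plan had 12 samples, background correction with inferred negative controls and a detection p filter. Without detection p-values, the planned fallback, normexp with offset 50, and the percentile filter were used, and the siLuc 2 column was dropped.

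The 24 lists were YAP/TAZ target genes, Hippo pathway and TEAD cofactors, KLF family, KLF5-linked genes, G1/S genes, G2/M genes, p53 target genes, apoptosis regulators, SRF/MRTF cytoskeletal genes, extracellular matrix and mesenchymal genes, TGF-beta response genes, integrins and focal adhesion, type I interferon response, NF-kB and inflammatory cytokines, ATF4 and unfolded protein response, cholesterol synthesis and SREBP2 targets, glycolysis and hypoxia, AP-1 and immediate early genes, endothelial, hepatocyte, epithelial and leukocyte markers, ribosomal proteins, and replication-dependent histones. Each gene was represented by its probe with the highest mean signal. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 72 tests against siLuc and over 72 between knockdowns, and again with an estimated correlation. A list's mean is the mean log2 change of its measured members.

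Genes were named by rule. For each knockdown against siLuc, these were the 3 targets, then the 10 highest and 10 lowest changes among probes past the threshold with a standard gene symbol and with every knockdown value on the same side of every siLuc value, at 1 probe per gene. Up to 4 members of each list past the threshold with the largest changes were added, and CCN1, CCN2, ANKRD1, AMOTL2, AXL, WWTR1, TEAD2, TEAD3, TEAD4, CCND1 and MKI67 were always included. Between knockdowns the 5 highest and 5 lowest were named, for all 3 knockdowns 5 in each direction, and for opposite changes up to 5 per pair. Gene symbols were current ones where the reference table gave them. Some genes that meet this rule are not reported here.

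Correlations of fold changes were set against 100 simulated data sets of unchanged groups sharing the siLuc arrays. In a self-test on all 35423 probes, added changes of 1.5-fold were recovered in 58.2, 56.7 and 65.7% of cases for siYAP1, siTEAD1 and siKLF5 against siLuc, 2-fold changes in 100, 98.5 and 100%, and 4-fold changes in 100% each. False calls made up 3.89, 4.49 and 6.35%. A shift of 0.3 added to the G2/M list gave a camera adjusted p of 1.51e-29, with 0 of 71 other tests called. The simulated probes varied independently, so this does not test camera where the genes of a list vary together. The folds were added to normalized values of probes drawn from all those tested, so the recovery is of changes in signal. Near background a change in RNA gives a smaller change in signal, and its recovery was not tested.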

Results

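Gene expression was measured in SK-Hep1, a human liver cancer cell line, after small interfering RNA (siRNA) had been directed at YAP1, TEAD1 or KLF5, with siLuc as the control siRNA. YAP1 is the transcriptional coactivator at the end of the Hippo pathway, TEAD1 is a DNA-binding partner of YAP1, and KLF5 is a zinc finger transcription factor. The comparisons address what each of these 3 factors contributes to expression in this line. Labelled cRNA made from the total RNA of each sample was hybridised to an Illumina HumanHT-12 bead array. Each of its 47231 probes gives a fluorescence signal, and a gene can have more than 1 probe. The labels give 3 samples per group, but the siLuc 2 column equalled the mean of siLuc 1 and siLuc 3 at all 47231 probes, within a relative tolerance of 1e-09. It was therefore not counted as a sample, which left 11 arrays, 2 of siLuc and 3 of each knockdown. The median signal per array was 107 to 125, and 14487 to 15491 probes per array (30.7 to 32.8%) lay above that array's background bound. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The precision of every value is limited by the number of arrays. The smallest two-sided p that an exact permutation test can give is 0.2 for 2 arrays against 3 and 0.1 for 3 against 3, so calls rest on limma's adjusted p.

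YAP1 RNA was lower on the arrays labelled siYAP1 and was not measurably different on the others. The YAP1 probe (chromosome 11, band 11q22.1d-q22.2a in the file's annotation, which names no genome build) read 1040 and 1530 on the 2 siLuc arrays and 375, 402 and 448 on the 3 siYAP1 arrays. The group means were 1280 ± 344 (SD, n = 2) and 408 ± 36.9 (SD, n = 3), and the fitted level was 28.2% of siLuc (log2 change −1.83, SE 0.16, limma adjusted p = 2.2e-06, exact permutation p = 0.2). YAP1 averaged 1450 ± 312 (SD, n = 3) in siTEAD1, with a log2 change of 0.14 (adjusted p = 0.806), and 1240 ± 258 (SD, n = 3) in siKLF5, with a log2 change of −0.06 (adjusted p = 0.949). TEAD1 (chromosome 11, band 11p15.2c) was close to background everywhere: its brighter probe read 142 and 137 on the siLuc arrays, passing the bound on 1 of them, and 123, 123 and 105 on the siTEAD1 arrays. That probe changed by −0.44 on the log2 scale in siTEAD1 (SE 0.15, adjusted p = 0.142), and the other TEAD1 probe stayed under the bound on every array. KLF5 (chromosome 13, band 13q22.1a) was under the bound on every array, at 126 and 120 in siLuc and at 105, 106 and 105 in siKLF5 (log2 change −0.28, SE 0.12, adjusted p = 0.405). The arrays therefore check the siYAP1 label only, and the siTEAD1 and siKLF5 arrays are named by their labels, with knockdown not measured.

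**Figure D1:**
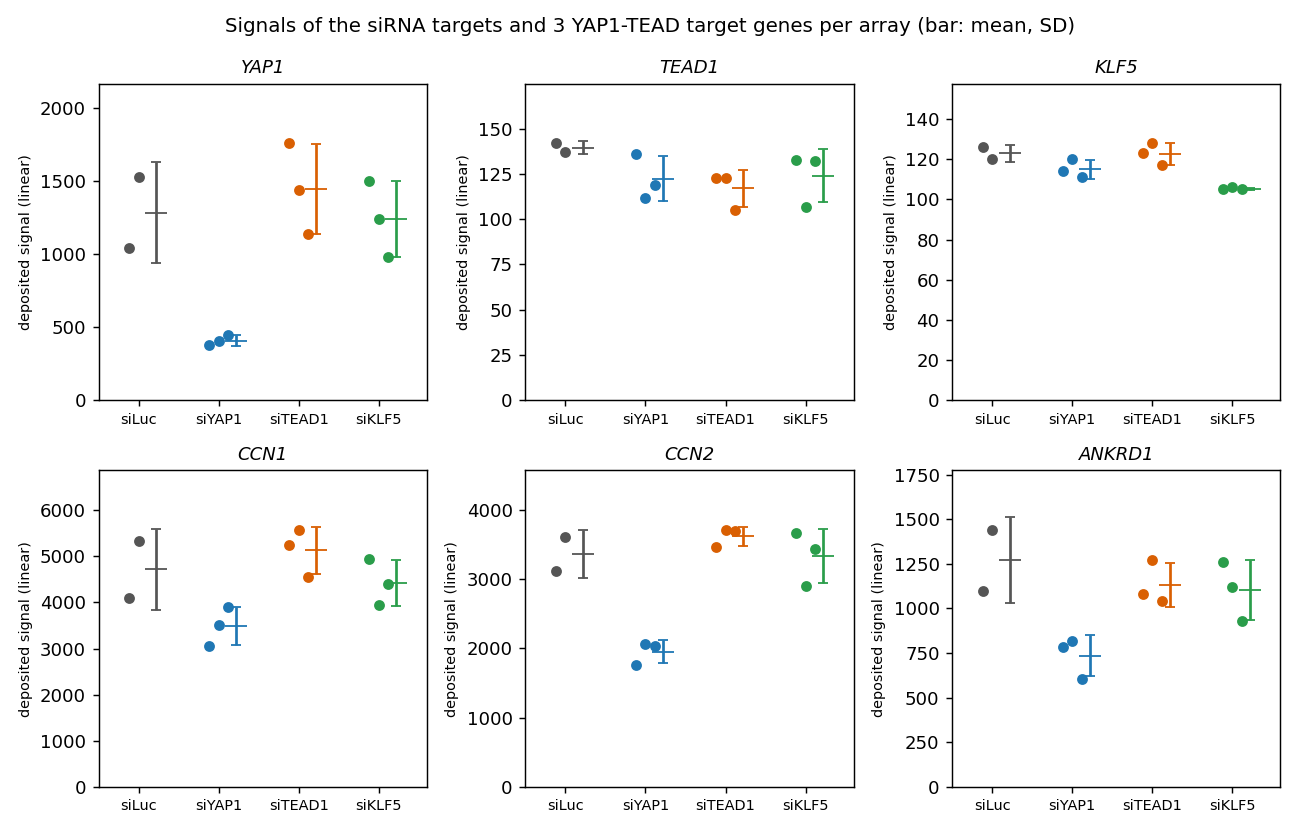
Deposited signal (linear axis) of the 3 targeted genes and of CCN1, CCN2 and ANKRD1 on each array (points), with the group mean and SD (bars; n = 2 for siLuc, n = 3 for each knockdown). YAP1 lies at 375 to 448 on the siYAP1 arrays against 1040 and 1530 on the siLuc arrays, while TEAD1 and KLF5 lie near background in every group.

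The siYAP1 arrays had much more RNA of the matrix protease MMP9 and much less of NPPB, the precursor of B-type natriuretic peptide. MMP9 (band 20q13.12b) averaged 875 ± 73.9 (SD, n = 3) against 129 ± 10.9 (SD, n = 2) in siLuc, at least 6.12-fold higher, with a fitted log2 change of 3.18 (SE 0.13, adjusted p = 4.28e-11). NPPB (band 1p36.22a) averaged 132 ± 10.4 (SD, n = 3) against 762 ± 177 (SD, n = 2), at least 5.05-fold lower (log2 change −3.04, SE 0.17, adjusted p = 3.68e-09). A fold given as at least a value divides the bright group's mean deposited signal by the highest background bound among the arrays of a group in which the gene was not above background, while log2 changes are of background-corrected, normalized values. TDO2, which opens the tryptophan degradation pathway, rose 4.27-fold (1080 against 267), COL7A1, the collagen of anchoring fibrils, rose 4.06-fold (970 against 262), and CD74, the invariant chain of MHC class II, rose 3.47-fold (3310 against 964). The transporter ABCC3 rose at least 3.08-fold by 1 probe, while its other probe gave a log2 change of −0.11. Among genes that fell, the long noncoding RNA SFTA1P dropped by 2.07 on the log2 scale, the keratin KRT34 by 1.6, the alkaline phosphatase ALPL by 1.53 and IGFBP3, which binds insulin-like growth factors, by 1.25 (SE 0.17, adjusted p = 0.000215). Of 35423 probes tested, 847 were higher and 575 lower in siYAP1.

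Among commonly used YAP1-TEAD readouts, CCN2 and ANKRD1 fell in siYAP1, and most of the wider list did not pass. Of 22 measured YAP/TAZ target genes, 5 fell, 1 rose and 16 did not pass the threshold (adjusted over the list alone, 8 fell and 2 rose). CCN2, a secreted matricellular protein, fell to 1950 ± 172 (SD, n = 3) from 3360 ± 349 (SD, n = 2), a log2 change of −0.81 (SE 0.12, adjusted p = 0.000381), and ANKRD1, a cardiac ankyrin repeat protein, changed by −0.90 (SE 0.17, adjusted p = 0.00551). CCN1, a relative of CCN2, changed by −0.45 (adjusted p = 0.041), a call that ended whichever of the 5 arrays was left out (adjusted p = 0.0515 to 0.249). Other members did not pass: AXL changed by −0.26 (adjusted p = 0.364) and AMOTL2 by 0.04. The list was lower by limma's camera test with its preset correlation (mean log2 change −0.22, adjusted p = 0.000941), with adjusted p = 0.17 with an estimated correlation. Without siLuc replicate 3 its mean was −0.11 (adjusted p = 0.149). Among Hippo pathway genes, WWC1, an upstream regulator, fell by 1.02 and WWTR1, which encodes the YAP1 paralog TAZ, changed by 0.07. TEAD4 changed by −0.62 (adjusted p = 0.095), while its dimmer probes read 117 and 155 against 125 and 161 in siLuc. TEAD3, not above background on either siLuc array, changed by 0.23, and TEAD2 changed by 0.61 (adjusted p = 0.0184). Of 25 members 1 rose and 2 fell, YAP1 among them (adjusted over the list alone, 3 rose and 4 fell), with camera adjusted p = 0.47.

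By camera the lists of DNA replication and mitosis genes were lower in siYAP1 with the preset correlation only, and most of their members did not pass. Of 42 G1/S genes 8 fell and none rose (adjusted over the list alone, 10 fell), among them the replication factor GINS2 (log2 change −0.92, adjusted p = 0.000421) and the exonuclease EXO1 (−0.75, adjusted p = 0.00112, with −0.03 by 1 other probe), and camera gave adjusted p = 5.39e-09 (adjusted p = 0.084 with an estimated correlation). Of 54 G2/M genes 9 fell and none rose (adjusted over the list alone, 19 fell), including the spindle protein CKAP2L (−0.74, adjusted p = 0.000656), with camera adjusted p = 1.9e-10 (adjusted p = 0.0508 with an estimated correlation). MKI67, a proliferation marker, changed by −0.29 (adjusted p = 0.236) and CCND1, cyclin D1, by −0.35 (adjusted p = 0.156). Some histone genes went the other way: 6 of 13 replication-dependent histone genes rose and 1 fell (adjusted over the list alone, 7 and 1), with H4C8 up 3.5-fold and H2AC18 up 1.92-fold. Camera gave adjusted p = 7.61e-05 for that list (adjusted p = 0.108 with an estimated correlation).

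The matrix, TGF-beta, integrin and interferon lists were higher in siYAP1, with a minority of the members of each past the threshold. Of 29 extracellular matrix and mesenchymal genes 6 rose and none fell (adjusted over the list alone, 10 rose), led by COL6A1 (log2 change 1.22, adjusted p = 9.76e-06), SPARC (1.06) and COL3A1 (0.93), with camera adjusted p = 3.1e-08. Of 18 TGF-beta response genes 7 rose and 1 fell (adjusted over the list alone, 7 and 1), with camera adjusted p = 1.66e-06. The helix-loop-helix inhibitors ID2 (1.64) and ID1 (1.29) and the matrix protein TGFBI (1.25) rose, while the other ID1 probe gave 0.19. Of 21 integrin and focal adhesion genes 5 rose and none fell (adjusted over the list alone, 13 rose and 1 fell), with ITGB4 at 1.31, ITGA2 at 1.23 and ITGAV at 1.23 (camera adjusted p = 5.3e-09). Of 27 type I interferon response genes 7 rose and none fell (adjusted over the list alone, 13 rose), with OAS2 at 0.99 and IRF9, part of the interferon-activated transcription complex, at 0.90 (camera adjusted p = 3.14e-08). The 3 other OAS2 probes gave log2 changes of 0.12, 0.05 and 0.39, and 1 other ITGB4 probe gave 0.09. With an estimated correlation these 4 lists kept their calls (adjusted p = 0.0124, 0.0124, 0.0379 and 0.0271 in the order given).

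The remaining lists did not pass the camera test in siYAP1, although each but the endothelial and leukocyte markers held members that changed. Of 23 p53 target genes 2 rose (adjusted over the list alone, 4 rose; adjusted p = 0.185), TP53I3 by 0.94 and TP53INP1 by 0.70 on the log2 scale. Of 22 apoptosis regulators 3 rose and 2 fell (adjusted over the list alone, 3 and 2; adjusted p = 0.868). Of 20 SRF/MRTF cytoskeletal genes 3 fell (adjusted over the list alone, 2 rose and 3 fell; adjusted p = 0.477), including TAGLN, an actin-binding protein, at −0.78, while its other probes gave −0.35 and 0.12. The stress gene DDIT4 rose 3.03-fold in the ATF4 and unfolded protein response list (1 rose and 1 fell of 23; adjusted over the list alone, 1 and 4; adjusted p = 0.308). Of 21 AP-1 and immediate early genes 6 rose and 1 fell (adjusted over the list alone, 7 and 2; adjusted p = 0.0569), with the phosphatase DUSP6 at 1.22. In the NF-kB and inflammatory cytokine list 2 rose and 2 fell of 26 (adjusted over the list alone, 4 and 3; adjusted p = 0.665), with a mean of 0.04 and a median of −0.01. Among 14 hepatocyte markers 1 rose (adjusted over the list alone, 1; adjusted p = 0.299), SERPINA1, the secreted antitrypsin, by 1.66, with 0.17 by 1 other probe. Among 16 epithelial markers 1 rose (adjusted over the list alone, 1 rose and 1 fell; adjusted p = 0.308), the keratin KRT19, 2.14-fold.

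In the same comparison, cholesterol synthesis genes (1 rose and 2 fell of 23; adjusted over the list alone, 2 and 3) gave adjusted p = 0.06 and glycolysis and hypoxia genes (1 and 1 of 24; adjusted over the list alone, 2 and 2) gave 0.615. KLF5-linked genes (1 rose and 2 fell of 11; adjusted over the list alone, 1 and 4) gave adjusted p = 0.615, with PTGES, a prostaglandin synthase, at 1.15. Their mean was −0.03, and 0.01 with arrays scaled to 1 median. The KLF family (1 rose of 13; adjusted over the list alone, 1) gave 0.47 and ribosomal proteins (1 rose of 51; adjusted over the list alone, none) gave 0.47. No marker passed among 9 endothelial genes (adjusted over the list alone, none; adjusted p = 0.615) or 14 leukocyte genes (adjusted over the list alone, 1 rose; adjusted p = 0.615). The siYAP1 count of 1422 probes was 350 without siLuc replicate 1, 736 to 891 without 1 of the siYAP1 replicates and 3172 with all 12 columns as deposited. With arrays scaled to 1 median, 662 of 866 called probes (76.4%) were higher, against 59.6% with quantile normalization.

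The siTEAD1 arrays also showed higher MMP9 and lower NPPB, together with a strong rise of the cytokine IL6. MMP9 averaged 563 ± 61.5 (SD, n = 3), at least 3.94-fold higher than in siLuc (log2 change 2.50, SE 0.13, adjusted p = 3.33e-09). IL6, an inflammatory cytokine, rose 3.65-fold to 2600 ± 231 (SD, n = 3) from 716 ± 32.7 (SD, n = 2), a log2 change of 1.87 (SE 0.14, adjusted p = 2.81e-07). COXFA4L3 rose 4.99-fold (7420 against 1480), although 1 of its other probes gave a log2 change of −0.30. CRISPLD2 rose 3.85-fold, CD74 rose 3.82-fold and TGFBI rose 3.74-fold. NPPB averaged 175 ± 9.76 (SD, n = 3) against 762 ± 177 (SD, n = 2), a change of −2.47 (SE 0.17, adjusted p = 6.67e-08). SFTA1P fell by 1.24 on the log2 scale, IGFBP1, which binds insulin-like growth factors, by 1.23 and KRT34 by 1.18. In all, 558 probes were higher and 447 lower.

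The YAP1-TEAD readouts were not measurably lower in siTEAD1. CCN1 averaged 5130 ± 513 (SD, n = 3), with a log2 change of 0.09 (SE 0.12, adjusted p = 0.835). CCN2 averaged 3620 ± 144 (SD, n = 3), with a change of 0.08 (SE 0.12, adjusted p = 0.866), and ANKRD1 changed by −0.22 (SE 0.17, adjusted p = 0.679). Of 22 YAP/TAZ target genes 1 rose and 2 fell (adjusted over the list alone, 3 and 2), with CRIM1, a membrane protein that binds bone morphogenetic proteins, at −0.79 (adjusted p = 0.00514). The list's mean was −0.02, its median 0.02 and its camera adjusted p 0.956. The mean was 0.02 with arrays scaled to 1 median. Of the other readouts, AXL changed by −0.32 (adjusted p = 0.272), AMOTL2 by 0.04 and WWTR1 by −0.36 (adjusted p = 0.302). TEAD4 changed by −0.73 (adjusted p = 0.0561), while its dimmer probes read 117 and 165 against 125 and 161 in siLuc. TEAD2 changed by 0.49 (adjusted p = 0.0706) and TEAD3, not above background on either siLuc array, by 0.30 (adjusted p = 0.214). Of 25 Hippo pathway genes 1 rose (adjusted over the list alone, 4 rose and 2 fell), with camera adjusted p = 0.665.

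The 2 cell cycle lists were lower in siTEAD1, with a minority of their members past the threshold. Of 54 G2/M genes 20 fell and none rose (adjusted over the list alone, 33 fell), with the mitotic kinase AURKA at −0.75 (adjusted p = 0.00212) and CKAP2L at −0.81 (adjusted p = 0.000392), and camera gave adjusted p = 2.78e-24 (0.0124 with an estimated correlation). Of 42 G1/S genes 7 fell (adjusted over the list alone, 16 fell), with GINS2 at −1.08 (adjusted p = 0.000117) and camera adjusted p = 3.29e-13 (0.0376 with an estimated correlation). MKI67 changed by −0.42 (adjusted p = 0.0831) and CCND1 by −0.23 (adjusted p = 0.474). Replication-dependent histones held 1 gene that rose, H4C8, 2.18-fold, and 1 that fell of 13 (adjusted over the list alone, 1 and 2), with adjusted p = 0.138.

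The inflammatory and interferon lists were higher in siTEAD1, with a minority of their members past the threshold. Of 26 NF-kB and inflammatory cytokine genes 9 rose and none fell (adjusted over the list alone, 13 rose), including IL6, IL1A at 1.15 (adjusted p = 6.08e-05) and the NF-kB-induced gene TNFAIP2 at 1.44 (adjusted p = 0.000131), and camera gave adjusted p = 1.23e-11 (0.0124 with an estimated correlation). Of 27 interferon response genes 8 rose (adjusted over the list alone, 13 rose), with camera adjusted p = 5.39e-09 (0.0238 with an estimated correlation). The example OAS2 changed by 0.84 (adjusted p = 0.00715, but 0.088 without siLuc replicate 3), and its 3 other probes gave 0.04, 0.09 and 0.43. The matrix, TGF-beta and integrin lists were higher as well, with most members not past the threshold. Of 29 extracellular matrix genes 4 rose (adjusted over the list alone, 9 rose), led by SPARC at 1.36 and COL6A1 at 0.68 (camera adjusted p = 1.12e-06, and 0.0124 with an estimated correlation). Of 18 TGF-beta response genes 3 rose (adjusted over the list alone, 6 rose and 1 fell), with TGFBI at 1.90 and the receptor TGFBR2 at 0.91 (camera adjusted p = 7.61e-05, and 0.0238 with an estimated correlation). Of 21 integrin and focal adhesion genes 4 rose (adjusted over the list alone, 7 rose and 2 fell), with ITGAV at 1.32 and ITGA2 at 1. Camera gave adjusted p = 2.85e-05 for that list (adjusted p = 0.114 with an estimated correlation), and its mean of 0.30 was 0.18 without siLuc replicate 1.

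The other lists did not pass in siTEAD1 with all measured genes as background. Of 16 epithelial markers 4 rose (adjusted over the list alone, 5 rose and 3 fell; adjusted p = 0.06, but 0.0117 against genes above background only). Of 23 p53 target genes 3 rose (adjusted over the list alone, 3; adjusted p = 0.308), with the stress cytokine GDF15 at 0.89. SERPINA1, at 1.53, was the 1 hepatocyte marker of 14 that rose (adjusted over the list alone, 1; adjusted p = 0.615). DDIT4, at 1.54, was the 1 ATF4 and unfolded protein response gene of 23 that rose (adjusted over the list alone, 2; adjusted p = 0.308). Of 20 SRF/MRTF genes 2 fell (adjusted over the list alone, 2; adjusted p = 0.665), with TAGLN at −0.97 and 0.15 by 1 other probe, and of 24 glycolysis and hypoxia genes 1 fell (adjusted over the list alone, 3 rose and 1 fell; adjusted p = 0.0836), the vasoactive peptide gene ADM at −0.81. Apoptosis regulators (2 rose and 3 fell of 22; adjusted over the list alone, 4 and 3) gave adjusted p = 0.868, and KLF5-linked genes (2 and 2 of 11; adjusted over the list alone, 2 and 2) gave 0.868. The KLF family (1 rose of 13; adjusted over the list alone, 1 and 1) gave 0.832. AP-1 genes (1 and 1 of 21; adjusted over the list alone, 2 and 2) gave 0.956, with a mean of 0.01, a median of −0.06 and a test direction of lower. Cholesterol genes (1 fell of 23; adjusted over the list alone, 1 fell) gave 0.537, with a mean of −0.04, or 0.02 with arrays scaled to 1 median. No member passed, over all probes or adjusted over the list alone, among 9 endothelial markers (0.665), 14 leukocyte markers (0.615) and 51 ribosomal proteins (0.92). The siTEAD1 count of 1005 probes was 286 without siLuc replicate 1, 593 without siTEAD1 replicate 2 and 2417 with all 12 columns. With arrays scaled to 1 median, 397 of 560 called probes (70.9%) were higher, against 55.5%.

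The siKLF5 arrays differed least from siLuc by count, with 94 probes higher and 124 lower. NPPB fell here too, to 230 ± 28.5 (SD, n = 3) from 762 ± 177 (SD, n = 2), a log2 change of −1.87 (SE 0.17, adjusted p = 1.52e-05). The metabolic enzyme gene AK4, an adenylate kinase, fell by 1.32 on the log2 scale, the secreted protein FAM3C by 1.27, and COL4A1, a basement membrane collagen, by 0.80 (adjusted p = 0.0018), and the corepressor LCOR fell 2.17-fold. For AK4, 1 of 3 other probes gave −0.03. RASD2, a Ras-family GTPase, rose 2.75-fold to 358 ± 15.8 (SD, n = 3) from 155 ± 3.39 (SD, n = 2), a log2 change of 1.46 (SE 0.12, adjusted p = 1.18e-05). CRISPLD2 rose 2.5-fold, the kinase gene SIK1 2.33-fold and TBC1D2 2.12-fold. The readouts CCN1 (−0.08, adjusted p = 0.877), CCN2 (−0.03, adjusted p = 0.956) and ANKRD1 (−0.23, adjusted p = 0.72) did not pass, and CCN2 gave 0.01 with arrays scaled to 1 median. Nor did TEAD2 (0.38, adjusted p = 0.307), CCND1 (0.23, adjusted p = 0.569) or MKI67 (−0.10).

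The inflammatory list was lower in siKLF5, with 4 members past the threshold. Of 26 NF-kB and inflammatory cytokine genes 4 fell and none rose (adjusted over the list alone, 10 fell and 1 rose), with the chemokine CXCL6 at −0.92 (SE 0.15, adjusted p = 0.00501), and camera gave adjusted p = 2.47e-07 (0.0238 with an estimated correlation). The other 3 were less secure: without siLuc replicate 1 the adjusted p was 0.582 for IL6 (−0.64), 0.215 for the chemokine CXCL8 (−0.57) and 0.549 for the chemokine CCL2 (−0.76). Genes of ATF4 and the unfolded protein response lay higher as a group, 19 of 23 above 0 with a mean of 0.20, though no member passed, over all probes or adjusted over the list alone (camera adjusted p = 9.78e-05, and 0.0238 with an estimated correlation). Of 24 glycolysis and hypoxia genes 2 fell (adjusted over the list alone, 6 fell), with camera adjusted p = 2.03e-05 (adjusted p = 0.0843 with an estimated correlation). The list's mean of −0.22 was −0.12 without siLuc replicate 1. The 2 members that fell were the collagen hydroxylase P4HA1 at −0.74 and the mitophagy receptor BNIP3 at −0.70, whose adjusted p without siLuc replicate 1 was 0.555 and 0.333, and the other P4HA1 probe gave −0.08.

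Several small list shifts in siKLF5 passed camera only with its preset correlation. Integrins (1 rose of 21; adjusted over the list alone, 8 rose and 1 fell; mean 0.23) had camera adjusted p = 3.93e-05, and adjusted p = 0.116 with an estimated correlation. The G1/S list (0 of 42 passed; adjusted over the list alone, 1 fell) had 0.00174 and adjusted p = 0.299 with an estimated correlation. The G2/M list (1 fell of 54; adjusted over the list alone, 3 fell) had 0.000746 and adjusted p = 0.262 with an estimated correlation. AP-1 genes (0 of 21; adjusted over the list alone, 5 rose) had 0.0113 and adjusted p = 0.186 with an estimated correlation, and cholesterol genes (2 rose of 23; adjusted over the list alone, 2 rose) had 0.0282 and adjusted p = 0.156 with an estimated correlation. SRF/MRTF genes (0 of 20; adjusted over the list alone, 3 rose) had 0.0306 and adjusted p = 0.262 with an estimated correlation. The members that passed were ITGA3 in the integrin list (0.73) and INSIG1 (0.76) and HMGCS1 (0.66) in the cholesterol list; without siLuc replicate 1 the adjusted p of ITGA3 was 0.64 and that of INSIG1 0.678, and without siLuc replicate 3 that of HMGCS1 was 0.239. Each of these 6 list calls also ended when a siLuc array was left out: without siLuc replicate 1 the integrin, AP-1 and SRF/MRTF calls ended (means 0.11, 0.07 and 0.04), and without siLuc replicate 3 the G1/S, G2/M and cholesterol calls ended (means −0.07, −0.08 and 0.10).

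The other lists did not pass in siKLF5. Extracellular matrix genes (COL6A1 rose and COL4A1 fell of 29; adjusted over the list alone, 2 and 1) gave adjusted p = 0.0773, with COL6A1 at 0.59 (adjusted p = 0.0336, a call that ended whichever of the 5 arrays was left out, with adjusted p = 0.0634 to 0.237). Among 23 p53 target genes 1 passed (adjusted over the list alone, 1 rose; adjusted p = 0.329), GDF15 at 0.70 (adjusted p = 0.0158, but 0.342 without siLuc replicate 1). Epithelial markers (1 rose of 16; adjusted over the list alone, 2 rose and 1 fell) gave 0.607. No member passed over all probes in the following lists. Adjusted over the list alone, YAP/TAZ targets had 1 higher and 1 lower (camera adjusted p = 0.47), Hippo genes 1 higher (0.367), the KLF family 1 higher (0.47), apoptosis regulators 3 lower (0.537), TGF-beta genes 2 higher and 2 lower (0.956) and hepatocyte markers 1 lower (0.456). Adjusted over the list alone, none passed among KLF5-linked genes (0.21), interferon genes (0.993), endothelial markers (0.513), leukocyte markers (0.998), ribosomal proteins (0.185) or histones (0.868). The TGF-beta list had a mean of 0.00, a median of −0.01 and a test direction of higher, and its mean was 0.01 with arrays scaled to 1 median. The interferon list had a mean of 0.00, a median of 0.04 and a test direction of lower. The siKLF5 count of 218 probes was 40 without siLuc replicate 1, 748 without siLuc replicate 3, 69 and 79 without siKLF5 replicates 2 and 3, and 933 with all 12 columns. With arrays scaled to 1 median, 54 of 88 called probes (61.4%) were higher, against 43.1%.

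**Figure D2:**
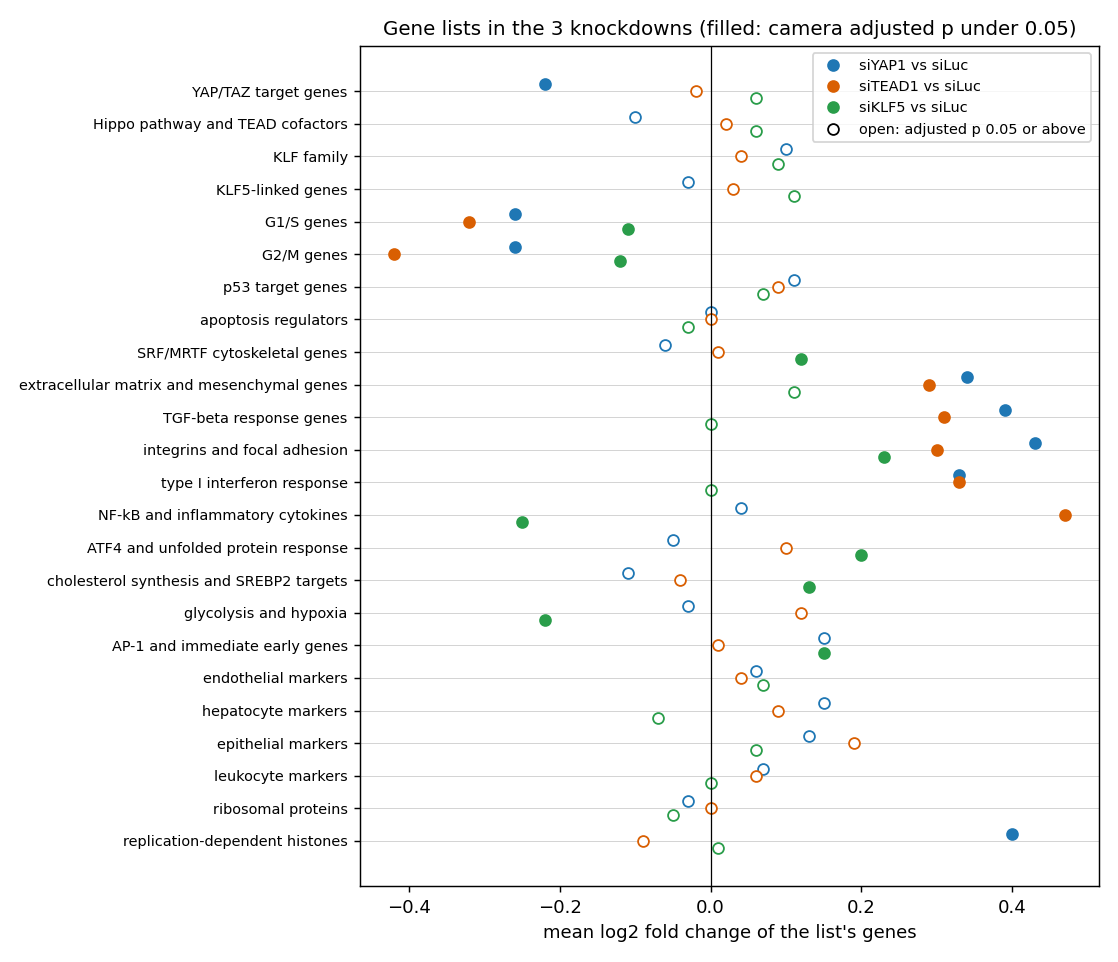
Mean log2 fold change against siLuc (horizontal axis) of the measured members of each of the 24 gene lists, by knockdown; filled circles mark lists with a camera adjusted p under 0.05 with the preset correlation. The G2/M list lies at −0.26 in siYAP1, −0.42 in siTEAD1 and −0.12 in siKLF5, and the NF-kB list at 0.47 in siTEAD1 and −0.25 in siKLF5.

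Compared directly, without the siLuc arrays, siYAP1 and siTEAD1 parted most clearly in inflammatory and histone genes. IL6 was 3.73-fold lower in siYAP1 than in siTEAD1 (745 ± 56 against 2600 ± 231, SD, n = 3 each; adjusted p = 2.73e-07), and the leukocyte integrin chain ITGB2, the growth factor CSF3 and the cytokine IL1B had log2 differences of −1.39, −1.39 and −1.28. Of 26 NF-kB genes 7 were lower in siYAP1 (adjusted over the list alone, 15 lower and 1 higher; camera adjusted p = 2.32e-16, and 0.0058 with an estimated correlation). Of 13 histone genes 6 were higher (adjusted over the list alone, 9 higher), with H2AC18 higher by 1.35. Camera gave adjusted p = 1.99e-16 for the histone list (0.0122 with an estimated correlation). H2AC19, a histone gene outside that list, was higher by 1.27. ID2 was higher by 1.31 and the kinase CDK6 by 1.27. The ATF4 and unfolded protein response list was lower in siYAP1, with 1 member of 23 past the threshold (camera adjusted p = 0.000258, and 0.0223 with an estimated correlation). The G2/M list was higher, with 0 of 54 past it (camera adjusted p = 1.85e-07, but 0.0798 with an estimated correlation). CCN2 was lower in siYAP1 than in siTEAD1 (−0.89, SE 0.10, adjusted p = 0.000111), as was CCN1 (−0.55, SE 0.11, adjusted p = 0.019), while ANKRD1 did not pass (−0.68, SE 0.16, adjusted p = 0.0517). The YAP/TAZ list was lower in siYAP1 (3 lower and 1 higher of 22; adjusted over the list alone, 7 and 1; camera adjusted p = 1.92e-06, but adjusted p = 0.0589 with an estimated correlation). In all, 123 probes were higher and 101 lower, and the count of 224 was 105 and 112 without siYAP1 replicates 2 and 1, 143 without siYAP1 replicate 3 and 134 without siTEAD1 replicate 2.

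Against siKLF5, siYAP1 had higher MMP9 (at least 6.12-fold), COXFA4L3 (log2 difference 2.22, with 0.24 by 1 other probe), ABCC3 (at least 3.08-fold by 1 probe, with −0.04 by the other) and TDO2 (1.97). YAP1 (−1.77), SFTA1P (−1.49), IGFBP3 (−1.47) and KRT34 (−1.39) were lower. Interferon genes (8 of 27 higher; adjusted over the list alone, 10; camera adjusted p = 5.09e-10), TGF-beta genes (7 higher and 1 lower of 18; adjusted over the list alone, 9 and 1; 2.87e-07) and extracellular matrix genes (8 higher and 1 lower of 29; adjusted over the list alone, 8 and 2; 2.39e-05) were higher as lists in siYAP1. ATF4 and unfolded protein response genes (1 higher and 8 lower of 23; adjusted over the list alone, 1 and 11; 2.11e-06) and cholesterol genes (3 lower of 23; adjusted over the list alone, 8 lower; 5.46e-06) were lower as lists. These 5 calls held with an estimated correlation (adjusted p = 0.0183, 0.0122, 0.0159, 0.0153 and 0.0183), as did that of the NF-kB list (6 of 26 higher; adjusted over the list alone, 11 and 2; camera adjusted p = 3.14e-07, and 0.0183). The YAP/TAZ list was lower (6 lower and 1 higher of 22; adjusted over the list alone, 9 and 2; camera adjusted p = 5.45e-06, but adjusted p = 0.067 with an estimated correlation). In all 797 probes were higher and 554 lower, and the count of 1351 was 814, 731 and 776 without siYAP1 replicates 1, 2 and 3 and 704 and 710 without siKLF5 replicates 2 and 3.

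The siTEAD1 and siKLF5 arrays differed strongly in inflammatory genes. Of 26 NF-kB genes 16 were higher in siTEAD1 and none lower (adjusted over the list alone, 20 higher), with IL6 5.69-fold higher (2600 ± 231 against 473 ± 32.3, SD, n = 3 each; adjusted p = 6.98e-10), and camera gave adjusted p = 1.28e-27 (0.00194 with an estimated correlation). COXFA4L3 was 8.63-fold higher (7420 against 878), although 1 of its other probes gave 0.15, MMP9 was at least 3.94-fold higher and TGFBI 3.96-fold higher. Lower in siTEAD1 were COX10, an assembly factor for cytochrome c oxidase (log2 difference −1.49), SLC18A3, a vesicular acetylcholine transporter (−1.45), and GFPT1, which opens the hexosamine pathway (−1.26). Of 54 G2/M genes 18 were lower in siTEAD1 (adjusted over the list alone, 25; camera adjusted p = 2.16e-16, and 0.0183 with an estimated correlation). Interferon genes (7 of 27; adjusted over the list alone, 10; 6.49e-11) and glycolysis and hypoxia genes (7 of 24; adjusted over the list alone, 10; 9.48e-09) were higher as lists in siTEAD1, with 0.016 and 0.0223 as adjusted p with an estimated correlation. TGF-beta genes (4 of 18; adjusted over the list alone, 6 and 1; 0.000197) and extracellular matrix genes (4 of 29; adjusted over the list alone, 5; 0.000801) were higher too, with 0.0195 and 0.0223. In all 501 probes were higher and 386 lower, and the count of 887 was 503 without siTEAD1 replicate 2 and 469 and 484 without siKLF5 replicates 2 and 3.

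**Figure D3:**
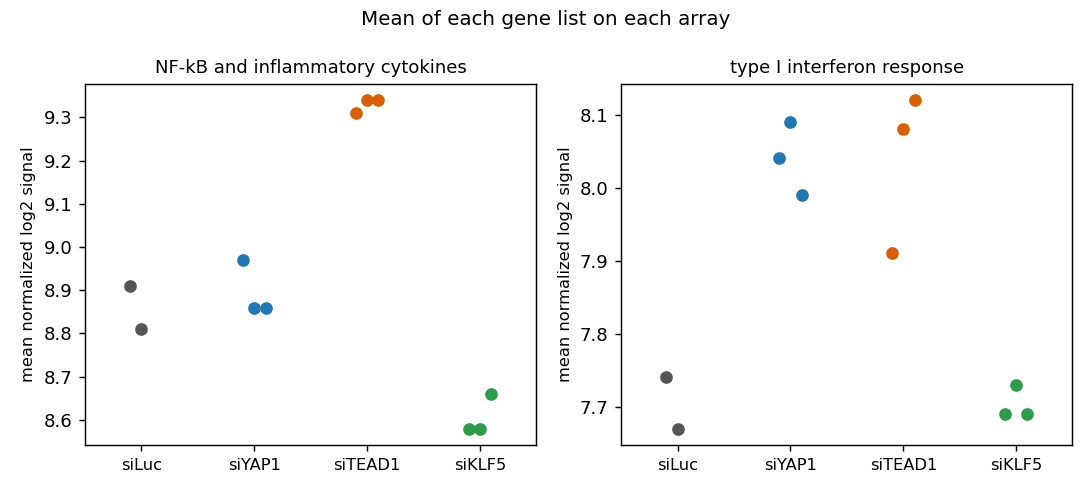
Mean normalized log2 signal (vertical axis) of the NF-kB and inflammatory cytokine list (left) and of the type I interferon list (right) on each of the 11 arrays, 1 point per array. For the NF-kB list the 3 siTEAD1 arrays lie above every other array and the 3 siKLF5 arrays below; for the interferon list siYAP1 and siTEAD1 both lie above siLuc and siKLF5.

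Many of the same genes moved in siYAP1 and siTEAD1. Fold changes against siLuc correlated across the 35423 probes at r = 0.78, where unchanged groups simulated against the same 2 siLuc arrays gave 0.60, and genes are not independent replicates. The covariance was 0.0409 against a simulated 0.0115, an excess of 0.0294. The simulation gave each probe the same spread in all groups. The SD of the log2 difference was 0.257 between the 2 siLuc arrays and 0.192 to 0.273 between arrays of the same knockdown. The simulated r and covariance may therefore be too low, and the excess too high. In both comparisons 348 probes were higher and 230 lower, where independent lists of these sizes would share 13.3 and 7.26, a value that leaves out the shared siLuc arrays. Simulated unchanged groups that share those arrays had 0 shared calls on average over 20 data sets, though no probe was changed in them. With siYAP1 and siTEAD1 each set against a different siLuc array, r was 0.33 or 0.40, and in the same way 0.09 or 0.16 for siYAP1 and siKLF5 and 0.12 for siTEAD1 and siKLF5 either way. The siLuc arrays are too few to split with 2 on each side, so part of the excess may come from the shared controls. The 578 shared probes became 150 without siLuc replicate 1, 1048 without siLuc replicate 3 and 373 without siTEAD1 replicate 2. For siYAP1 and siKLF5, r was 0.54 and 96 probes were shared (52 higher and 44 lower, against 2.25 and 2.01 for independent lists; covariance 0.0241). For siTEAD1 and siKLF5, r was 0.56 and 89 were shared (48 and 41, against 1.48 and 1.56; covariance 0.0235). Both of these r lie under the simulated 0.60, and both covariances above the simulated 0.0115. These 2 counts were 11 and 12 without siLuc replicate 1 and 493 and 415 without siLuc replicate 3. The first was also 60 and 52 without siYAP1 replicates 1 and 2 and 39 and 43 without siKLF5 replicates 2 and 3, and the second 154 and 58 without siTEAD1 replicates 1 and 2 and 29 and 35 without siKLF5 replicates 2 and 3.

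In all 3 knockdowns, 36 probes of 35 genes were higher and 30 probes of 28 genes were lower, against the same 2 siLuc arrays. No value expected without change was computed for this overlap itself. Each pair shared 0 calls in the simulated unchanged groups, but those sets hold no changed probe. The shared arrays can bring calls together, so the overlap does not show a common response. These counts were 5 and 3 without siLuc replicate 1 and 175 and 204 without siLuc replicate 3, which held 24 of the 36 and 26 of the 30. They were 60 and 54 without siTEAD1 replicate 1, 22 and 16 without siYAP1 replicate 2, 15 and 11 without siKLF5 replicate 2 and 18 and 12 without siKLF5 replicate 3, and the lower count was 19 without siYAP1 replicate 1. CRISPLD2, a secreted protein with a CAP domain, rose by 1.57 in siYAP1, 1.94 in siTEAD1 and 1.32 in siKLF5 on the log2 scale, and the Cdc42 effector gene CDC42SE2 by 1.18, 1.20 and 1.38, with 0.29, 0.32 and 0.26 by its other probe. NPPB fell at least 5.05-fold in siYAP1, where it was not above background, and by 2.47 and 1.87 in siTEAD1 and siKLF5. These 3 genes kept their calls in every comparison whichever array was left out. VSTM1 changed by −1.55, −1.09 and −0.82 and POLR3G, a subunit of RNA polymerase III, by −0.92, −1.1 and −0.77, and both siKLF5 calls ended without siLuc replicate 1 (adjusted p = 0.477 and 0.485).

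**Figure D4:**
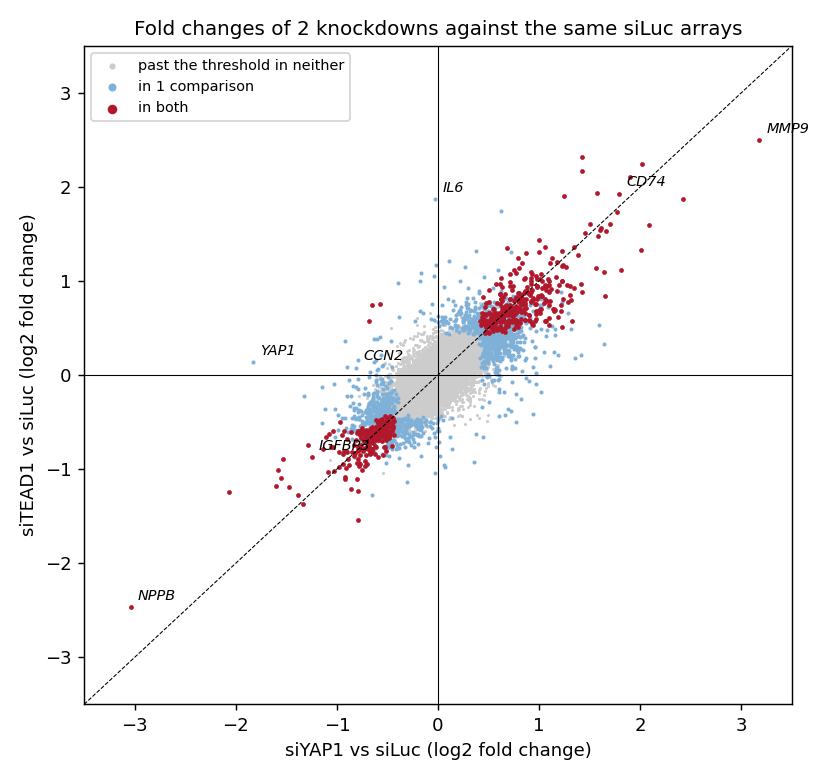
Log2 fold change against the same siLuc arrays in siYAP1 (horizontal axis) and siTEAD1 (vertical axis), 1 point per probe, coloured by whether it passed the threshold in neither, 1 or both comparisons; the dashed line marks equal change. MMP9 and NPPB lie at opposite ends, each with a smaller change in siTEAD1 than in siYAP1, while IL6 lies high and YAP1 and CCN2 lie to the left, off the line.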

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

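The tests of the shared siLuc arrays, of the siLuc arrays for the NF-kB list, of an innate response, of a uniformly weaker response and of other TEAD family members were chosen after the results they measure were seen.

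Some genes changed against siLuc in opposite directions in 2 knockdowns, and the direct difference between these knockdowns also passed the threshold. For siYAP1 and siTEAD1 there were 3 such probes. They were both probes of the leukocyte integrin chain ITGB2 (brighter probe −0.65 and 0.74 on the log2 scale, direct difference −1.39, adjusted p = 8.49e-06) and the fatty acid transporter SLC27A2 (−0.68 and 0.57, direct difference −1.25, adjusted p = 1.44e-05). The directions against siLuc were less secure than the differences. Without siLuc replicate 1 the adjusted p of the brighter ITGB2 probe was 0.106 in siYAP1 and 0.0836 in siTEAD1, and without siYAP1 replicate 2 it was 0.0532 in siYAP1. For SLC27A2 it was 0.0845 in siYAP1 without siLuc replicate 3, and in siTEAD1 0.478 without siLuc replicate 1 and 0.0669 without siTEAD1 replicate 2.

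For siYAP1 and siKLF5 there were 5 such probes, of COXFA4L3 (1.43 and −0.79, direct difference 2.22, adjusted p = 1.4e-08), the glutaminyl cyclase QPCT (0.62 and −0.73), COL4A1 (0.45 and −0.80) and, with 2 probes, the apoptosis inhibitor BIRC3 (0.59 and −0.58 for the brighter). For siTEAD1 and siKLF5 there were also 5, of COXFA4L3 (2.32 and −0.79, direct difference 3.11, adjusted p = 1.4e-10), IL6 (1.87 and −0.64), QPCT (0.50 and −0.73) and, with 2 probes, the chemokine CXCL6 (0.64 and −0.92). Without siLuc replicate 1, adjusted p in siKLF5 was 0.47 for COXFA4L3, 0.582 for IL6, 0.212 for QPCT and 0.536 for BIRC3, in siYAP1 0.307 for COL4A1, and in siTEAD1 0.348 for CXCL6 and 0.111 for QPCT. Without siLuc replicate 3 it was 0.0558 for QPCT and 0.087 for BIRC3 in siYAP1 and 0.181 for QPCT in siTEAD1. Leaving out a knockdown array ended further calls. In siKLF5 this held for COXFA4L3 without replicates 2 and 3 (0.0871 and 0.0995), for QPCT without replicate 2 (0.0604), and for IL6 and BIRC3 without any of the 3 (0.102 to 0.141 and 0.0507 to 0.184). In siYAP1 it held for COL4A1 without replicates 1 and 2 (0.102 and 0.0899) and for BIRC3 without replicate 3 (0.0509), and in siTEAD1 for CXCL6 and QPCT without replicate 2 (0.0818 and 0.149).

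The overlap between siYAP1 and siTEAD1, 578 probes changed the same way, was weighed against 2 technical explanations. Shared siLuc arrays would leave siYAP1 minus siKLF5, which uses no siLuc array, centred on 0 at the 1005 probes called in siTEAD1. Its median, signed by the siTEAD1 change, was 0.26, and 824 of the 1005 (82%) had the sign of the siTEAD1 change, so the shared arrays are not the whole cause, though part of the overlap may come from them. With the number of probes above background per array as a covariate, 98.7% of the median siYAP1 change of the shared probes was left and 548 of 578 (94.8%) passed in both, which argues against array signal level. A response shared by YAP1 and TEAD1, or by siRNAs other than siLuc, stays open as a hypothesis, and the count was 150 without siLuc replicate 1, 1048 without siLuc replicate 3 and 373 without siTEAD1 replicate 2.

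The NF-kB list was higher in siTEAD1 and lower in siKLF5. The separation of siTEAD1 from siKLF5 does not rest on the siLuc arrays, since siTEAD1 minus siKLF5, which uses none of them, was 0.73 (SE 0.04). That difference cannot test the directions against siLuc, which depend on the siLuc arrays. A single siTEAD1 array is not the cause of the rise in siTEAD1, since at least 98.9% of the siTEAD1 mean of 0.47 was left whichever was omitted (0.47 to 0.51). An innate response that raises interferon genes alongside stays open, since the interferon list was also higher in siTEAD1 than in siKLF5 (0.33, SE 0.06). Against siYAP1, where interferon genes had risen too, the interferon difference was 0.00, with an upper 95% limit at 30.4% of the NF-kB difference of 0.44 (SE 0.04). An effect of either siRNA on other genes was not tested and stays open, as does a biological role of TEAD1 or KLF5.

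The readouts CCN1, CCN2 and ANKRD1 fell in siYAP1 and not in siTEAD1, although the CCN1 call in siYAP1 ended whichever of the 5 arrays was left out (adjusted p = 0.0515 to 0.249). Compared directly, CCN1 and CCN2 differed between the knockdowns (adjusted p = 0.019 and 0.000111) and ANKRD1 did not pass (0.0517). A uniformly weaker response to siTEAD1 stays open only for genes that fell in siYAP1. It does not hold over all genes, since the NF-kB list was higher in siTEAD1 than in siYAP1 (0.44, SE 0.04). The ratio of siTEAD1 to siYAP1 change was at percentile 0.23 of random sets of 3 probes that fell in siYAP1, but these 3 genes were singled out after their values were seen, and the 2 other YAP/TAZ targets that fell in siYAP1, IGFBP3 and CRIM1, were lower in siTEAD1 too (−0.87 and −0.79), IGFBP3 with adjusted p = 0.0864 without siLuc replicate 3. Another TEAD family member acting in place of TEAD1 stays open as well, since TEAD4 averaged 797 on the siTEAD1 arrays by its brightest probe (117 and 165 by its others). So does a TEAD1 that was not depleted, because the TEAD1 probes lay near background.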

How the results depend on the processing

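The 12-column fit, the filter on probes above background on at least 3 arrays, the background covariate and the list background of genes above background were chosen after seeing the data. The other alternatives were planned. Among main results, 284 values kept their direction and side of the threshold or stayed within 1.5 times the reported count, 82 moved, 2 became weaker, 1 stronger and 4 reversed. Among named genes these were 3797 the same, 397 weaker, 14 stronger and 18 reversed, and among lists 1206 the same, 28 weaker, 26 stronger and 51 reversed.

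With arrays scaled to 1 median in place of quantile normalization, 866, 560 and 88 probes were called in siYAP1, siTEAD1 and siKLF5 against siLuc (reported: 1422, 1005 and 218), 134 between siYAP1 and siTEAD1 and 1281 among the 4 groups. Shared calls were 351 for siYAP1 and siTEAD1, 39 for siYAP1 and siKLF5 and 37 for siTEAD1 and siKLF5. The cause was not tested. With all 12 columns as deposited the 3 comparisons against siLuc gave 3172, 2417 and 933, and the 4 groups 3851. Shared calls were then 1480, 458 and 425, and the TEAD1 level in siTEAD1 was −0.43 with adjusted p = 0.0465. The mean column adds an array's worth of degrees of freedom with no spread of its own. Counts between knockdowns rose less with it. They went from 224 to 284 for siYAP1 with siTEAD1 and from 1351 to 1763 for siYAP1 with siKLF5. For siTEAD1 with siKLF5 they went from 887 to 1164. The degrees of freedom are common to all comparisons, so they alone do not explain the larger rise against siLuc. The fit also counts siLuc as 3 arrays in place of 2, although the mean column holds no separate measurement. This makes the standard error too small in comparisons against siLuc and leaves the array numbers between knockdowns as they were. How much of the larger rise comes from this was not tested.

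Stricter thresholds call fewer probes by construction. At least 2-fold changes left 137, 89 and 21 probes against siLuc and 37, 93 and 82 between knockdowns, in the order siYAP1 with siTEAD1, siYAP1 with siKLF5 and siTEAD1 with siKLF5. Adjusted p under 0.01 left 528, 386 and 76 and then 103, 590 and 413. Averaging the probes of a gene tests fewer units and gave 946, 658, 117 and 144 for the 3 comparisons against siLuc and for siYAP1 with siTEAD1. With only the 2 groups compared in the fit, siTEAD1 against siLuc gave 324, siYAP1 against siLuc 1506 and siYAP1 with siKLF5 2191, and the cause was not tested. With the covariate, siKLF5 against siLuc gave 581, siYAP1 with siTEAD1 397, and shared calls with siKLF5 were 260 for siYAP1 and 243 for siTEAD1. These shared calls were 62 and 57 with eBayes trend and robust, and 58 for siTEAD1 and siKLF5 with array weights. The cause was not tested.

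With the correlation within lists estimated, 12 of 24 list calls held, and the YAP/TAZ list in siYAP1, at −0.22, had adjusted p = 0.17. By limma's fry, which does not compare a list with other genes, that list passed (adjusted p = 0.0319), as did the other lists called in siYAP1 and siTEAD1. In siKLF5 the G1/S, G2/M, AP-1, cholesterol and SRF/MRTF calls did not hold by fry (adjusted p = 0.155, 0.139, 0.0762, 0.0532 and 0.0806). With lists tested against genes above background only, the side of the threshold changed for 2 of 72 tests, to adjusted p = 0.0117 for epithelial markers in siTEAD1 and 0.112 for SRF/MRTF genes in siKLF5. The cause was not tested. The call of the YAP/TAZ list was also lost without siLuc replicate 3 (−0.11, adjusted p = 0.149).

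Some values close to 0 changed sign, and none of these was a called gene or list. With arrays scaled to 1 median, siKLF5 gave 0.01 for CCN2, 0.03 for AXL, 0.01 for TGF-beta genes and 0.00 for leukocyte markers. KLF5-linked genes in siYAP1 gave 0.01, and in siTEAD1 the YAP/TAZ list and cholesterol genes gave 0.02 each. With the covariate, AXL in siKLF5 gave 0.01, and KLF5-linked genes in siYAP1, ribosomal proteins in siTEAD1 and leukocyte markers in siKLF5 gave 0.00 each. Apoptosis regulators gave 0.00 in siYAP1 and in siTEAD1 with no background correction, the authors' values, the replicate block and 12 columns. They gave −0.01 in siYAP1 with averaged probes and −0.01 in siTEAD1 with the filter on probes above background. AP-1 genes in siTEAD1 gave 0.00 with the block and with averaged probes. Interferon genes in siKLF5 gave −0.02 with the block, 0.00 with 12 columns and with the filter on probes above background, and −0.01 with averaged probes. With no filter on dim probes, TGF-beta genes in siKLF5 gave 0.01 and histones 0.00. The cause was not tested.

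Leaving out each array in turn gave ranges that were widest for the siLuc arrays. With 1 siLuc array left, it is assumed to vary like the other groups. Calls in siYAP1 ran from 350 without siLuc replicate 1 to 1998 without siLuc replicate 3, in siTEAD1 from 286 to 1411 and in siKLF5 from 40 to 748, with the same 2 arrays omitted. Between knockdowns the ranges were 105 (without siYAP1 replicate 2) to 277 (without siTEAD1 replicate 1) for siYAP1 and siTEAD1, 704 to 1164 (without siKLF5 replicates 2 and 1) for siYAP1 and siKLF5, and 469 (without siKLF5 replicate 2) to 1000 (without siTEAD1 replicate 3) for siTEAD1 and siKLF5. Probes differing among the 4 groups ran from 1454 to 2743 and list calls from 21 to 26. Correlations ran from 0.71 to 0.86 for siYAP1 and siTEAD1, 0.48 to 0.73 for siYAP1 and siKLF5 and 0.49 to 0.74 for siTEAD1 and siKLF5. Shared calls ran from 150 to 1048, 11 to 493 and 12 to 415, lowest without siLuc replicate 1 and highest without siLuc replicate 3. The level of YAP1 in siYAP1 stayed past the threshold at −2.00 to −1.64, and TEAD1 in siTEAD1 ran from −0.52 to −0.35 and KLF5 in siKLF5 from −0.37 to −0.20.

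Other values crossed 0 or approached it when arrays were left out. In siYAP1 AMOTL2 ran from −0.04 to 0.10, WWTR1 from −0.05 to 0.18, apoptosis regulators from −0.02 to 0.02, SRF/MRTF genes from −0.15 to 0.03, NF-kB genes from −0.01 to 0.10, glycolysis genes from −0.13 to 0.06 and ribosomal proteins from −0.08 to 0.01, while the YAP/TAZ list ran from −0.32 to −0.11. In siTEAD1 YAP1 ran from −0.04 to 0.33, KLF5 from −0.12 to 0.03, CCN1 from −0.03 to 0.22 and AMOTL2 from −0.03 to 0.10. Among its lists, YAP/TAZ targets ran from −0.12 to 0.09, Hippo genes from −0.03 to 0.08, the KLF family from −0.01 to 0.08, KLF5-linked genes from 0.00 to 0.07, apoptosis regulators from −0.04 to 0.01, SRF/MRTF genes from −0.08 to 0.10, AP-1 genes from −0.07 to 0.09 and ribosomal proteins from −0.05 to 0.04. In siKLF5 YAP1 ran from −0.24 to 0.13, CCN1 from −0.21 to 0.04, CCN2 from −0.08 to 0.01 and AXL from −0.17 to 0.14. Its YAP/TAZ targets ran from −0.05 to 0.16, TGF-beta genes from −0.04 to 0.00, interferon genes from −0.03 to 0.04, leukocyte markers from −0.04 to 0.03 and histones from −0.04 to 0.05. The cause was not tested.

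Of named probes called, 58 of 92 in siYAP1, 42 of 81 in siTEAD1 and 13 of 42 in siKLF5 stayed past the threshold whichever array was left out, and 27, 35 and 28 lost the call without siLuc replicate 1. All 10 named in each comparison between knockdowns stayed past it.

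Arrays with the same replicate number were no more alike than others, since the 15 pairs correlated at r = −0.27 to 0.35 after group means were removed, with 3 above 0.1, so the numbers were not taken to pair samples. With replicate number as a block, the counts were 1281, 857 and 206 against siLuc, 194, 1238 and 797 between knockdowns and 1909 among the 4 groups. The YAP1 level was −1.83 (adjusted p = 2.22e-05) and the YAP/TAZ list in siYAP1 −0.22 (adjusted p = 0.00209).

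The planned detection p filter, the slide block and the correction with inferred negative controls were not run, since the files give neither detection p-values nor slides, and the planned fallback correction is the reported fit. Signal over background limits what can be said of dim genes. Between 30.7 and 32.8% of probes per array lay above the bound of 127 to 151, KLF5 lay under it on every array, and changes of genes near the bound, such as TEAD1, are compressed by background.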

Other observations

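The MHC class II, retinoic acid and aryl hydrocarbon receptor lists were drawn up after the data had been seen, while their tests' predictions came before those tests.

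Of 10 measured genes of MHC class II, which present peptides to helper T cells, 4 rose in siYAP1 and none fell, alongside their chaperone CD74 (3310 against 964), which the list leaves out. HLA-DRA went from 1170 to 2970 (log2 change 1.35, adjusted p = 4.76e-06), HLA-DPA1 from 891 to 1880 (1.08), HLA-DMB from 300 to 634 (1.07) and HLA-DMA from 603 to 1090 (0.81). Their activator CIITA changed by 0.37 (adjusted p = 0.108), and HLA-DPB1, HLA-DOA and HLA-DQB1 were under the background bound on every array. The list mean was 0.59, with camera adjusted p = 9.81e-09 over the 6 tests of this part (0.00599 with an estimated correlation). In siTEAD1 2 members rose, HLA-DRA by 0.93 and HLA-DPA1 by 0.79, with a mean of 0.38 and camera adjusted p = 1.24e-05 (0.0132 with an estimated correlation). A rise of the MHC class II group with CD74 is therefore a hypothesis that may hold for both knockdowns. Arrays were not left out in turn for the lists of this part.

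A retinoic acid response, looked for because PLAAT4 had risen, stayed open in siYAP1. Of 12 members only DHRS3, a retinal reductase, passed (log2 change 1.20, adjusted p = 5.85e-06), and camera gave adjusted p = 0.114. In siTEAD1 DHRS3 again was the 1 member that rose (0.96), with camera adjusted p = 0.0349 and adjusted p = 0.0721 with an estimated correlation. Aryl hydrocarbon receptor targets, looked for because TDO2 makes a precursor of receptor ligands, had 4 of 7 members measured. In siYAP1 TIPARP rose by 0.57 (adjusted p = 0.0119), with camera adjusted p = 0.0283 and adjusted p = 0.0721 with an estimated correlation. In siTEAD1 TIPARP changed by 0.01 and the mean was 0.05 (camera adjusted p = 0.629). The other 3 members lay at background, NQO1 above the bound on 1 of 11 arrays and ALDH3A1 and UGT1A6 on none, so a response there stays open. PLAAT4 and ALDH1A3, which prompted the retinoic acid list, and CYP1B1 and TDO2, which prompted the other, were not among the measured members. With at most 1 measured member past the threshold in each list, neither response can be called more than a candidate.

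Other splits of the same arrays were counted for each comparison of groups with 3 arrays. Each pair of knockdowns allows 10 splits of 6 arrays, of which the real 1 alone gave as many probes, and these are too few for a share under 0.05. The real counts were 224 for siYAP1 and siTEAD1, 1351 for siYAP1 and siKLF5 and 887 for siTEAD1 and siKLF5, and the highest other counts were 0, 0 and 2. Over all 4 groups 2113 probes differed, and 1 of 100 drawn splits of the 11 arrays, the real split, gave as many, with 1808 as the highest other. This share is under 0.05 and is the lowest that 100 draws can give, so a chance assignment of these arrays to groups is unlikely. Chance differences between cultures cannot be excluded in this way, since the replicates may be technical.

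The deposited siLuc 2 column had a median signal of 117, between those of siLuc 1 (116) and siLuc 3 (119). It equalled their mean at every probe, and no measurement separate from those 2 arrays was deposited in it.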
